A study of Mus musculus with 6 samples.

How the data were processed

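Pancreatic islets are the endocrine cell clusters that hold the insulin-producing beta cells. Islets were isolated from C57BL/6 mice given normal food (control diet, 3 samples) or high-fat food (high-fat diet, 3 samples), and RNA from each of the 6 samples was sequenced. The sample labels state 22 weeks of diet, whereas the series design text states 27 weeks, and the difference could not be settled here. Per the labels' protocols, RNA was taken up in Trizol and total RNA libraries were made with a Vazyme kit for Illumina sequencing. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0 and StringTie 1.3.3 were used with the GRCm38 build; the notes as used here give no role or order. The annotation release, the strand setting and the test behind the p-values are not given in the sources used here.

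The deposited table held 54 gene rows. Per the file headers, it gives 1 FPKM column per sample (fragment counts scaled by transcript length and library size), the authors' group means and SDs, a p-value, a log2 fold change, a score and an effect size. The authors' group means and SDs and their log2 fold changes were recomputed from the FPKM columns, and all 54 rows agreed within 1e-09. The deposited log2 fold change is thus the log2 ratio of mean FPKM, high-fat diet over control diet, with no pseudocount. The deposited score, positive where the control diet was higher, differed from a signal-to-noise ratio (difference of means over the sum of SDs, each SD at least a set share of its mean) by a median of 0.365%. The largest difference was 7.86%, so that formula comes close to the score but does not reproduce every row. The authors gave no adjusted p-values in this table.

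The 54 rows are a picked part of the transcriptome. All 54 deposited p-values lay below 0.01, with a highest value of 0.00999, and no score was smaller in size than 1.00. The rows were sorted by p-value. The rule that picked them is not stated, and the values above describe the table only. Because the rows were chosen on these same libraries, a test over them is not independent evidence of their direction. Genes outside the 54 rows were not analysed here. Not every gene behind a count is reported by name here.

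Gene symbols were taken by Ensembl identifier from the reference table, in which all 54 identifiers were found. Gene positions are those of GENCODE mouse release M21 on GRCm38, 1-based. Of the 54 genes, 13 share exon bases with another annotated gene, and without a stated strand setting their reads cannot be told apart from those of the partner.

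The comparison of the diets was a limma 3.58.1 fit (R 4.3.3) on log2(FPKM + 1), with a mean of at least 1 FPKM over the 6 libraries required. This left 26 of the 54 rows; the other 28 were described by their values. Empirical Bayes variances followed a trend on mean level, tests were two-sided, and p-values were Benjamini-Hochberg adjusted over the list alone at a threshold of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used. Nothing in the labels says how many mice stand behind a library or that replicates are separate animals. The limma p-values therefore concern these samples only. Each rests mostly on a variance pooled over the 26 picked genes (prior degrees of freedom 46.4), and less on that gene's own spread.

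The design, the alternatives, the rule for named genes and 31 gene lists for islet cell types, other cells of an islet preparation and metabolic or stress processes were fixed before the data were examined. The rule named the 10 rows with the largest deposited log2 fold change in each direction whose replicates did not overlap between diets, plus every row in a fixed list, which gave 26 genes. Set tests were planned only for lists with at least 5 members among the rows of a full table; no list reached 5, so members were counted. The planned comparison of acinar, leukocyte and endothelial marker levels was not made, since none of the 54 rows is in those lists.

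Read depth is unknown, because the table gives FPKM and no totals, so no counting interval or detection floor can be given. Among the 15 lowest genes, the best-fitting share of between-library ratios that were ratios of small whole numbers (within 2%) was 40.0%, the same as for random ratios, so no read steps were recovered. An FPKM listed at 0 may be a failed estimate or too few reads.

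The fit was tested on simulated data: 100 tables with the means of the 54 genes and a within-group log2 SD of 0.219 were drawn, with 27 genes changed. It found 99.8% of tested genes changed by 1 on the log2 scale and 81.0% of those changed by 0.6. Of its calls, 2.64% were false. The simulated noise was independent, with the same SD for every gene and library. Shifts shared across genes, unequal variances and picked rows were not simulated, so these shares do not measure the fit on the real libraries. A second simulation drew 15000 genes with no difference between the diets, picked the 131 with a plain p-value under 0.01 and fitted those alone. Of the 131, 130 passed the adjusted threshold. The authors' picking rule is not known, and 17 of the 54 real rows had a plain p-value under 0.01. Alternatives covered the pseudocount, the filter, median centring, quantile normalization, an untrended variance, an ordinary variance per gene, the threshold and each library left out. Within-group scaling, a library-level covariate and quantile normalization of the named genes were added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.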

Results

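Islet RNA of mice on a high-fat diet, a common way to induce obesity in this strain, was compared with islet RNA of mice on normal food, with 3 libraries per diet. The values were FPKM for 54 genes, with the library as replicate (n = 3 for every mean ± SD below, unless single libraries are given). Read totals were not given, so the depth behind each value is unknown. The levels spanned a wide range, from a mean over the 6 libraries of 0.0632 FPKM for Lrtm2 to 33.2 FPKM for Hsph1.

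The series asks which islet transcripts differ between high-fat and normal feeding. Of the 54 listed genes, 36 had a higher and 18 a lower mean on the high-fat diet. The median level over the 6 libraries was 1.49 FPKM for the genes higher on the high-fat diet and 0.364 FPKM for those lower on it. Among the 26 genes with a mean of at least 1 FPKM, the 5 highest ratios of means, high-fat over control, were 8.18 for the small nucleolar RNA Snord73a, 3.27 for Arntl, a core transcription factor of the circadian clock, 3.11 for Cpne4, a copine, 2.82 for Mdm1, which encodes a centriole protein, and 2.78 for Defb1, an antimicrobial beta-defensin. The 3 tested genes that fell past the limma threshold were Oat, the mitochondrial ornithine aminotransferase, Tnfrsf12a, the receptor for the cytokine TWEAK, and Selenbp1, a selenium-binding protein gene. Has1 also had a lower mean on the high-fat diet, 0.777 against 1.24 FPKM, and did not pass.

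Of the 26 genes with a mean of at least 1 FPKM, 22 rose and 3 fell on the high-fat diet, and 1, Has1, did not pass the threshold (limma, Benjamini-Hochberg adjusted over the list alone). The log2 difference of Has1 was -0.33 (limma adjusted p = 0.059), and it passed under quantile normalization (-0.83, limma adjusted p = 1.1e-05) and with the library's median level as a covariate (-0.55, limma adjusted p = 2.1e-05). Rises on the log2(FPKM + 1) scale ran from 0.49 to 1.51, and standard errors over all 26 tested genes from 0.17 to 0.27. The 54 rows were picked on these same libraries, so this count is not independent evidence. In a simulation with no difference between diets, 99.2% of genes picked by a plain p-value under 0.01 passed the same threshold. The rule that picked the real rows is not stated, and 17 of the 54 had a plain p-value under 0.01. The 99.2% therefore shows what picking can do, not its share in these rows. The count fell from 25 to 13 without control diet replicate 2 and to 15 without high-fat diet replicate 3. It was 14 with an ordinary variance per gene. Quantile normalization gave 10 (6 higher, 4 lower), and the library's median level as a covariate gave 12 (8 higher, 4 lower). That level was the median over the 54 picked rows. As log2(FPKM + 0.1) it was 0.26, -0.63 and -0.43 in control and 0.45, 0.11 and 0.48 in high-fat libraries. The covariate fit can therefore take out part of a diet difference. Quantile normalization keeps only ranks among the 26 tested genes, so genes near the top can hardly show a rise. Because most tested genes rose, both fits can also add to a fall, which limits what the passes of Has1 show.

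Defb1 rose from 12.9 ± 2.15 FPKM in control islets to 35.8 ± 5.75 FPKM on the high-fat diet, a 2.78-fold difference with a limma log2 change of 1.41 (SE 0.24, adjusted p = 3.8e-06). Mdm1 rose from 15.7 ± 8.46 to 44.3 ± 15.2 FPKM, a 2.82-fold difference, and its control libraries alone ranged from 9.21 to 25.3 FPKM. Under quantile normalization, neither Defb1 (limma adjusted p = 0.33) nor Mdm1 (limma adjusted p = 0.56) passed the threshold. Both ranked among the highest of the tested genes, where a scaling by rank can hardly show a rise. With the library level as a covariate Mdm1 did not pass (limma adjusted p = 0.052). Cpne4, which encodes a calcium-dependent phospholipid-binding copine, rose 3.11-fold, from 0.666 ± 0.361 to 2.07 ± 0.383 FPKM. Mum1l1 rose 2.64-fold, from 1.22 ± 0.355 to 3.21 ± 0.578 FPKM. Snord73a, a small nucleolar RNA, was listed at 0, 0.409 and 0.602 FPKM in the control libraries and at 3.14, 2.50 and 2.63 FPKM in the high-fat libraries. Its ratio of means moved from 8.18 to 13.5 without control diet replicate 3 and to 5.45 without control diet replicate 1. Its annotated length is 68 bp and it lies within the span of Rps3a1, a ribosomal protein gene, so its FPKM is sensitive to single fragments and to reads of the host transcript.

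**Figure D1:**
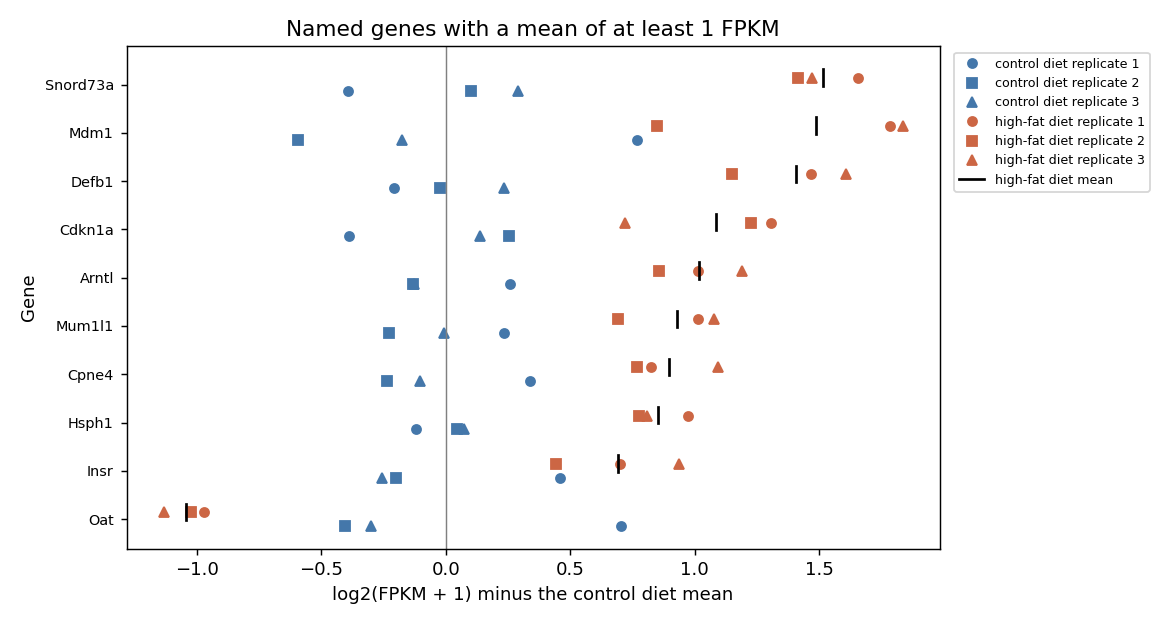
Level of each of the 10 named genes with a mean of at least 1 FPKM (rows) in each library, as log2(FPKM + 1) minus the mean of the control diet libraries; blue points are control diet, orange points are high-fat diet, shapes are replicates, and black ticks are high-fat means. The high-fat libraries lie above the control mean in 9 genes and below it in Oat, and Insr alone overlaps between diets. The naming rule allowed overlap only for genes in a fixed list. Hsph1 alone turns its direction under quantile normalization, which keeps only ranks among the 26 tested genes.

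Among the gene lists fixed in advance, 6 of 31 had a member among the 54 rows, for 7 genes in all, of which 6 were higher on the high-fat diet. From the circadian clock list (15 genes), Arntl was the one member present. It rose 3.27-fold, from 0.812 ± 0.293 to 2.66 ± 0.424 FPKM (limma log2 change 1.02, SE 0.19, adjusted p = 1.5e-05). From the cell cycle list (26 genes), Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 2.59-fold, from 2.38 ± 0.746 to 6.16 ± 1.47 FPKM (limma adjusted p = 0.00013). The other member, Ccne1, which encodes cyclin E1 and drives entry into DNA synthesis, averaged 0.603 ± 0.391 and 1.298 ± 0.300 FPKM. Ccne1 lay below the level tested and its replicates overlapped, with control diet replicate 1 at 1.04 FPKM; without that library its ratio of means moved from 2.15 to 3.39. These 2 members have opposite textbook roles in the cycle.

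From the insulin signalling list, Insr, the insulin receptor gene, rose 1.68-fold, from 6.46 ± 2.18 to 10.9 ± 2.02 FPKM (limma log2 change 0.69, SE 0.25, adjusted p = 0.010). Its diets overlapped, and the adjusted p was 0.066, 0.075 and 0.076 in limma fits without control diet replicate 2, control diet replicate 3 and high-fat diet replicate 3. Its log2 change was 0.08 under quantile normalization (limma adjusted p = 0.62) and 0.16 with the library level as a covariate (limma adjusted p = 0.41). From the heat shock list, Hsph1, an HSP110-class chaperone, rose 1.84-fold, from 23.4 ± 1.73 to 43.1 ± 3.29 FPKM under the deposited scaling. Its log2 change was 0.85, and 0.58 under median centring (limma adjusted p = 0.026). With the library level as a covariate it was 0.93 (limma adjusted p = 2.1e-05). Quantile normalization turned it to -0.07. Hsph1 ranked near the top of the 26 tested genes in every library, so that scaling could hardly show a rise. From the immediate early list, Jun, a subunit of the AP-1 transcription factor, averaged 0.444 ± 0.0818 FPKM in control and 0.759 ± 0.0316 FPKM in high-fat libraries, below the level tested. Its log2 ratio of means moved from 0.77 to 0.07 when FPKM was divided by each library's median over all 54 rows. For Hsph1, the centring instead used the median of log2(FPKM + 1) over the 26 tested genes, so the 2 shifts are not comparable. Of the 54 rows, 36 were higher on the high-fat diet, so their median can take out part of a rise.

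Oat was in the list of genes kept low in normal beta cells. It fell 2.55-fold by the ratio of means, from 8.55 ± 4.38 to 3.35 ± 0.246 FPKM (limma log2 change -1.04, SE 0.26, adjusted p = 0.00054). Control diet replicate 1 stood at 13.6 FPKM against 5.77 and 6.28 FPKM in the other controls, and without it the log2 change was -0.69. The other 25 lists had no member among the 54 rows. They include the islet hormones, beta cell identity genes, the unfolded protein response, inflammation, and the markers of acinar, duct, endothelial and stellate cells and leukocytes. Nothing can be said about the levels of those genes, which were not analysed here, nor about the cell make-up of the preparations from them.

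Genes below 1 FPKM held the largest deposited fold changes. Among those lower on the high-fat diet, Cer1, a secreted antagonist of BMP and Nodal signalling, was listed at 0.475, 0.187 and 0.200 FPKM in control libraries and at 0, 0 and 0.0116 FPKM in high-fat libraries. Igfbp6, an insulin-like growth factor binding protein, was listed at 1.96, 0.523 and 0.775 FPKM in control libraries and at 0, 0.0596 and 0 FPKM in high-fat libraries. In the authors' deposited table these are log2 fold changes of -6.21 (p = 0.0040) and -5.77 (p = 0.0085), taken without a pseudocount; with a pseudocount of 0.1 FPKM the log2 differences were -1.82 and -3.15. Without control diet replicate 1 the log2 ratio of means of Igfbp6 was -5.03. Without the 1 high-fat library above 0, neither gene has a finite ratio. Camp, which encodes the cathelicidin antimicrobial peptide of neutrophils, was listed at 0.372, 0.111 and 0.241 FPKM in control libraries and at 0, 0 and 0.0601 FPKM in high-fat libraries. Upk1b, a uroplakin gene, and Fcrlb, an Fc receptor-like gene, were also at 0 in 2 of 3 high-fat libraries and at or below 0.182 and 0.154 FPKM in control libraries. Clec11a, a secreted lectin gene and the row with the lowest p-value in the authors' deposited table (8.0e-05), was listed at 0.224, 0.116 and 0.125 FPKM in control and at 0.0473, 0 and 0.0443 FPKM in high-fat libraries.

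Of the other named low-level genes, Gnal, the olfactory-type stimulatory G protein alpha subunit, averaged 1.13 ± 0.384 FPKM in control and 0.223 ± 0.0830 FPKM in high-fat libraries, a ratio of 5.09. It shares exon bases with Mppe1 on the opposite strand. Kcng2, a modulatory subunit of voltage-gated potassium channels, was listed at 0.231, 0.486 and 0.410 FPKM in control and at 0.0895, 0.143 and 0 FPKM in high-fat libraries. Grik2, a kainate receptor subunit, averaged 0.300 ± 0.110 and 0.116 ± 0.0406 FPKM, and Lrtm2 averaged 0.0986 ± 0.0319 and 0.0278 ± 0.00922 FPKM. In the opposite direction, Gabrr2, a GABA receptor rho subunit, was listed at 0, 0.0332 and 0.0312 FPKM in control and at 0.208, 0.319 and 0.278 FPKM in high-fat libraries. Rasd2, a Ras-related small GTPase, averaged 0.278 ± 0.339 and 1.23 ± 0.303 FPKM. Its ratio of means moved from 4.42 to 14.96 without control diet replicate 1, which stood at 0.669 FPKM against 0.1001 and 0.0638 FPKM in the other controls. Me3, a mitochondrial malic enzyme, averaged 0.192 ± 0.0485 and 0.515 ± 0.0608 FPKM, and Fam78b averaged 0.0353 ± 0.0320 and 0.119 ± 0.0191 FPKM, with a ratio that moved from 3.36 to 6.40 without control diet replicate 1.

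**Figure D2:**
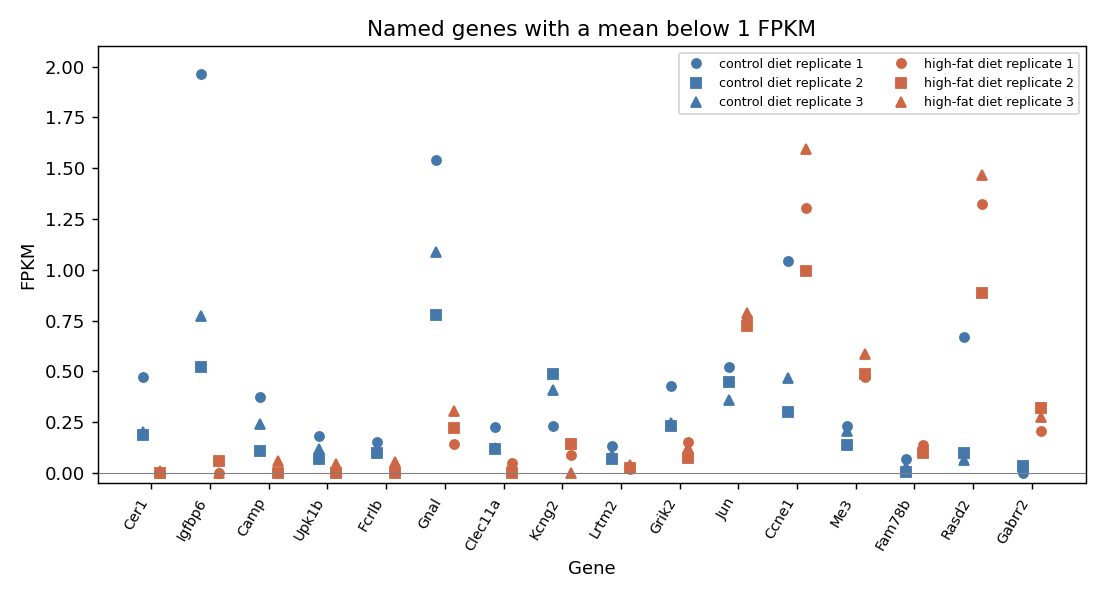
FPKM (vertical axis, linear) of the 16 named genes with a mean below 1 FPKM in each library; blue points are control diet, orange points are high-fat diet, and shapes are replicates. The 10 genes on the left are lower on the high-fat diet, the 6 on the right are higher, and only Ccne1 overlaps between diets. The naming rule allowed overlap only for genes in a fixed list.

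Across all 54 rows, the lowest library of the higher diet lay above the highest library of the other diet in 51, of which 33 were higher and 18 lower on the high-fat diet. Chance alone gives 10% of unpicked genes such a separation with 3 against 3 libraries. The 54 rows all had a low deposited p-value and a large score on these same libraries, which favours separated replicates. The count of 51 therefore cannot be set against the 10% as evidence of a diet difference. The exceptions were Insr, Ccne1 and Kl, the gene of the co-receptor Klotho.

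On GRCm38 (GENCODE M21), Arntl (ENSMUSG00000055116) lies on chromosome 7 from 113207465 to 113314126, and Oat (ENSMUSG00000030934) on chromosome 7 from 132557478 to 132576398. Defb1 (ENSMUSG00000044748) lies on chromosome 8 from 21776599 to 21795185, Mdm1 (ENSMUSG00000020212) on chromosome 10 from 118141811 to 118168997, and Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727. Insr (ENSMUSG00000005534) lies on chromosome 8 from 3122061 to 3279617, Igfbp6 (ENSMUSG00000023046) on chromosome 15 from 102144362 to 102149511, and Cer1 (ENSMUSG00000038192) on chromosome 4 from 82881751 to 82885148. These are protein-coding genes, and their FPKM values are per gene, not per exon or isoform. Arntl, Mdm1 and Cdkn1a share exon bases with annotated transcripts on the opposite strand, as do Kcng2, Me3 and Jun, and their values are uncertain to that extent.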

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

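The within-group scaling, the library-level covariate and the quantile values of named genes were chosen after seeing the data. The count of 25 of 26 tested genes (22 higher, 3 lower) was within 1.5 times of its value under pseudocounts of 0.1 and 0.01, median centring, an untrended variance, a threshold of 0.1 and within-group scaling. It was 54 (36 higher, 18 lower) with no filter on low values and 10 with a minimum mean of 5 FPKM, in both cases all genes tested. It was 10 (6 higher, 4 lower) under quantile normalization, 14 with an ordinary variance per gene and 12 (8 higher, 4 lower) with the library level as a covariate. Leaving out 1 library gave 13 to 25 genes, with 13 without control diet replicate 2 and 15 without high-fat diet replicate 3; the cause of these 2 drops was not tested. The median log2 change of the tested genes was 0.70, against 0.43 after median centring and 0.08 after quantile normalization. Both scalings assume that most genes do not differ, which a list picked for differences does not meet. Quantile normalization over the tested rows keeps only ranks, which leaves genes at the top, such as Hsph1, little room to rise. The covariate was itself the median over the 54 picked rows, so that fit can take out part of a diet difference. Because most tested genes rose, the quantile and covariate fits can also add to a fall. Quantile normalization turned the direction of 7 tested genes, none past the threshold afterwards, among them Hsph1, at -0.075; median centring, within-group scaling and the covariate turned none. All 54 deposited rows had p under 0.01, so that stricter limit and the recomputed folds left 54 of 54. Of 213 recomputed values of the named genes, 54 of untested low genes moved by more than their spread. For untested genes the starting value was the log2 ratio of mean FPKM without a pseudocount. The spread, and the value with a pseudocount of 0.1, were on log2(FPKM + 0.1), so part of these moves comes from the change of measure. Median centring of untested genes divided FPKM by the library's median over all 54 rows. Of the 213 values, another 6 (Insr 4 times, Mdm1 and Defb1 once each) lost the threshold, and 1 turned. The other 152 kept their direction and threshold call or, for untested genes, stayed within their spread. Their size could still change: Snord73a, at a log2 change of 1.51, gave 3.11 with a pseudocount of 0.1 and 0.71 under quantile normalization. Set tests and their alternatives were not run, since no list had 5 members. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 25 genes, 1 split gave as many, counting the real one, and the highest other gave 0; 10 splits are too few for a share under 0.05, and the rows were picked for the real split. Unknown depth limits the 28 rows below 1 FPKM most, and 9 of the 54 rows hold a 0 in at least 1 library.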

Other observations

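The limma fits with all libraries and with 1 left out, the gene count under quantile normalization, and the comparison of SDs were planned. The genes of the next paragraph, the quantile values of single genes and the covariate fit were chosen after the results were seen. So were the other tests in this part.

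Values of further genes follow, with no theme tested. Gabarapl1, an autophagosome protein of the Atg8 family, rose from 18.4 ± 5.27 to 32.3 ± 4.82 FPKM (n = 3), and Nrbf2, a subunit of the autophagy lipid kinase complex, from 1.83 ± 0.443 to 2.95 ± 0.455 FPKM. Fkbp5, a co-chaperone and a classical glucocorticoid-induced gene, rose 2.098-fold, from 6.30 ± 3.19 to 13.2 ± 1.77 FPKM. Tbc1d4, a regulator of glucose transporter traffic, rose 1.83-fold and Kl rose 2.11-fold. Tnfrsf12a fell from 4.52 ± 0.387 to 2.17 ± 0.368 FPKM, and Selenbp1 from 3.91 ± 0.583 to 1.96 ± 0.135 FPKM. In limma, these 7 changes had adjusted p-values from 0.00065 (Fkbp5) to 0.025 (Nrbf2), over a list picked on the same libraries. With 1 library left out, 4 of the 5 rises lost the threshold in some fits: Nrbf2 in 4 of 6 (limma adjusted p from 0.090 to 0.13), Kl in 2 (0.067 and 0.051), Tbc1d4 in 1 (0.066) and Gabarapl1 in 1 (0.052). Under quantile normalization none of the 5 rises passed the threshold (limma adjusted p from 0.069 for Tbc1d4 to 0.91 for Nrbf2), and the directions of Gabarapl1 and Kl turned. With the library level as a covariate none of the 5 passed either (limma adjusted p from 0.19 for Gabarapl1 to 0.40 for Kl), whereas Tnfrsf12a and Selenbp1 passed in both fits. The quantile and covariate fits rest on picked rows, most of which rose, so they can take out part of a rise and add to a fall. The log2 change of Tnfrsf12a was -0.80, against -1.40 under quantile normalization and -0.74 with the covariate. For Selenbp1 it was -0.72, against -1.09 and -0.85. These passes therefore do not show that the falls hold better than the rises. Dnajb4, an Hsp40-class co-chaperone, was listed at 0.601 ± 0.0489 and 0.949 ± 0.102 FPKM. Prdm16, a transcription regulator, stood at 0.618 ± 0.0766 and 0.386 ± 0.0347 FPKM, and Itgb6, an integrin subunit, at 0.295 ± 0.0246 and 0.159 ± 0.0196 FPKM.

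Control diet replicate 1 was the highest of the 3 control libraries in 46 of the 54 rows. Its median ratio to the mean of the other controls was 1.58 in the 36 genes higher on the high-fat diet and 1.65 in the 18 genes lower on it (quartiles 1.26 and 1.91). Islets closer to the high-fat state would have given a ratio below 1 in the second group, so the 1.65 argues against that explanation. A single scaling factor for the library, with noise equal to that of the other controls, is also argued against. Over 25 tested genes the SD of the log2 ratios of control diet replicate 1 was 2.04 times that between control replicates 2 and 3, where equal noise gives 0.87. The 95% bootstrap interval was 1.26 to 2.93 over genes, which are not independent. Cdkn1a, Hsph1 and Defb1 had ratios of 0.549, 0.878 and 0.787 beside 2.31 for Mdm1. A scaling factor in a library noisier than the others could also give more than 0.87, and with depth unknown it stays open. A shift of many but not all transcripts in this library, technical or biological, stays open, and whether it extends beyond these picked rows is not known.

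In 41 of 54 genes the deposited p-value was smaller than a plain comparison of the same FPKM values gives, and in 13 it was larger. All 54 deposited values lay below 0.01, whereas an ordinary linear model on log2(FPKM + 1) gave 17 genes under an unadjusted 0.01 and 49 under 0.05; for Kl the unadjusted values were 0.0084 in the authors' deposited table and 0.072 from the linear model. With the library's median level over these rows as a covariate, 18 of 54 genes lay under 0.01 and 34 under 0.05, and Kl stood at 0.44, which argues against an adjustment for that level as the explanation. Across genes, -log10 p of this fit correlated with the deposited -log10 p at Pearson r = 0.41 (permutation p = 0.0023, adjusted over 4 relations 0.0092), against r = 0.029 (permutation p = 0.84, adjusted 0.84) without the covariate, but r was 0.18 (permutation p = 0.20) without Clec11a and Mapkapk3, so the relation rests on those 2 genes. Spearman's rho was 0.18 (permutation p = 0.20, adjusted 0.40) with the covariate and 0.088 (permutation p = 0.52, adjusted 0.70) without it. The way the variance was estimated also mattered. A limma fit of all 54 rows, with variances pooled in part over these picked rows, gave 37 genes under an unadjusted 0.01 and 54 under 0.05. The authors' test is not stated, so whether it pooled variances over genes is not known. A term built from all genes of the libraries was not tested and stays open.

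A list of 12 genes associated with mesothelial cells, the lining cells of the abdominal organs, was written after the rows were seen, is not among the 31 lists, and was not tested for enrichment. Its 3 members among the rows (Upk1b, Igfbp6 and Has1) had lower means on the high-fat diet, with control means of 0.123, 1.09 and 1.24 FPKM; Has1 did not pass the limma threshold (adjusted p = 0.059), and Upk1b and Igfbp6 lay below the level tested. Fewer such cells in the high-fat preparations, as the one source of these transcripts, would lower the 3 genes by about the same factor. The widest fold between any control and any high-fat library was 2.25 for Has1, whereas the narrowest was 8.78 for Igfbp6. The latter rests on a single value of 0.0596 FPKM beside 2 zeros, with read depth unknown, so it excludes nothing. Has1 and Igfbp6 are also expressed by fibroblasts, and other mesothelial markers were not analysed here, so a lower share of these cells stays open.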
